A study of Cavia porcellus with 27 samples.

How the data were processed

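The series holds RRBS libraries from the prefrontal cortex of 27 female guinea pigs, 1 library per animal, and the groups were taken from the labels: 7 saline and 7 betamethasone animals at PND1, 7 and 6 at PND14. Per the labels' protocols, libraries were made from 100 ng of DNA with an Ovation RRBS kit and an EpiTect bisulfite kit. Per the submitters' processing notes, Trim Galore, Bismark 0.16.0, Bowtie2 2.3.4.3 and SAMtools 1.9 were used. The caller of differential CpGs, its filters and the genome build are not given in the sources used here.

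The authors deposited 1 table per age. Per the file headers, each row gives a scaffold, a position, the read coverage of the CpG under treatment codes 1 and 0, the methylated read count under the same codes, a methylated fraction for case and for control, a first p-value, a second p-value and an FDR, and at PND14 a difference in percentage points. Code 1 is the case and code 0 the control, because the deposited counts divided by the deposited coverage give those fractions. Case was read as betamethasone and control as saline, and with 1 value per treatment, coverage and counts were read as sums over its animals. No label or header states either reading, but the series record names the saline group as the control. If case were saline, every direction given here would turn round. The deposited FDR goes with the second p-value and not with the first, and the test behind each is not given in the sources used here. Every listed CpG has an FDR under 0.05 and at least 10 reads in each treatment, so the tables are lists of calls. CpGs that were tested and not called are not analysed here, and neither are values per animal.

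Depth limits what each level can show. Summed coverage per CpG ran from 10 to 1811 reads for betamethasone and from 10 to 1955 for saline at PND1, and from 10 to 471 and 10 to 472 at PND14. Wilson 95% intervals and counting errors come from summed reads. They cover counting error only, since reads are neither independent molecules nor independent animals, and a single animal with many reads can carry a summed level. Whether positions count from 0 or 1 is not given in the sources used here, so they are printed as deposited. The gene table at hand belongs to another assembly (mCavPor4.1), so its coordinates were not used.

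Levels and differences (betamethasone minus saline) were recomputed from methylated reads and coverage. The authors' calls were used with no new test per CpG for the main counts. Clusters are CpGs on a scaffold less than 1000 bp apart, with the sign of the mean difference as their direction. The share of higher clusters was tested with an exact two-sided binomial test, the shares of the ages with a two-sided Fisher's exact test, and runs of direction by permuting signs over CpGs 100000 times. These tests, the clusters and the alternatives tied to them were fixed before the data were examined. Intervals of mean differences are from 10000 bootstrap draws of clusters. All clusters of a treatment come from the same animals, so these p-values and intervals leave out variation between animals.

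The rule for named items took, per age, the 10 largest mean gains and 10 largest mean losses among genes with at least 2 called CpGs that all moved the same way, or at least 1 where fewer than 10 exist. Because no gene could be assigned, clusters took the place of genes after the tables had been seen, and PND14 gains needed the allowance for single CpGs. Regions were picked for their size, so their differences are biased upward in size. The 18 gene lists fixed in advance, the overlap of genes and the promoter shares were not tested for lack of an annotation of this build. Also chosen after the data were seen were the dense blocks (CpGs less than 100000 bp apart, at least 100 of them), strand pairs, one-way clusters, classes of level and Fisher's exact test per CpG with Benjamini-Hochberg adjustment.

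The tests were checked on simulated data. Reads were drawn with no difference between treatments, independently for each CpG, and tested with fewer permutations than the data. The permutation p was under 0.05 for adjacent CpGs in 2.5% of 40 runs at PND1 coverage and 5% at PND14. For one-way clusters it was so in 0% and 10%. Neighbouring CpGs of the data share reads and animals, so these draws do not check the tests against that dependence. Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.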

Results

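DNA methylation was measured by reduced representation bisulfite sequencing (RRBS) in the prefrontal cortex of 27 female guinea pigs (Cavia porcellus). RRBS cuts DNA at a restriction site and sequences short, CpG-rich fragments after bisulfite treatment, which turns unmethylated cytosine but not methylated cytosine into a base read as T. The mothers had received saline or betamethasone, a synthetic glucocorticoid given in pregnancies at risk of preterm birth to speed maturation of the fetal lung, on gestational day 50/51. Offspring were sampled on postnatal day (PND) 1, with 7 animals per treatment, or on PND14, with 7 saline and 6 betamethasone animals. The design compares betamethasone with saline at each age, and the series title names methylation signatures that are conserved between newborn and juvenile animals. Each age has a table of the CpGs that the authors called different, with 1 coverage and 1 count of methylated reads per treatment. These were read as sums over the animals of a treatment, which no source used here states. The tables' case was read as betamethasone, because the series record names the saline group as the control. No header names the treatment of case or control, and every direction below rests on the reading of case as betamethasone. No value of a single animal was analysed here, so no spread between animals stands beside any value. A level below is the percentage of summed reads that were methylated, and an SD is over the CpGs of a region. CpGs of a region can lie on the same reads, so a small SD does not show that a difference is precise. Positions are on numbered scaffolds of a genome build not given in the sources used here, so no gene, exon or promoter is assigned to any region. Median coverage per CpG was 112 summed reads for betamethasone and 117 for saline at PND1, and 64 and 72 at PND14.

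At PND1 the region with the largest gain lay on scaffold_10 at 35166305 to 35166362. Its 4 listed CpGs averaged 34.7% methylation after saline and 84.1% after betamethasone, a difference of 49.3 points (SD 2.56), at 17 to 19 reads per CpG and treatment, so that none of its CpGs has 20 reads in both treatments. On scaffold_1 at 73507716 to 73507778, 5 CpGs averaged 7.86% after saline and 31.8% after betamethasone, 23.9 points higher (SD 8.30). Of the 10 leading gains, the one with most listed CpGs was on scaffold_1 at 12189503 to 12189617. All 18 of its CpGs were higher, which the rule for picking regions requires. Their means were 26.6% and 50.3%, a difference of 23.7 points (SD 7.01). On scaffold_5 at 23258443 to 23258488, 5 CpGs averaged 67.8% after saline and 89.1% after betamethasone (21.4 points, SD 1.83). The most deeply read of the leading gains, on scaffold_0 at 3190833 to 3190902, had 134 to 185 reads per CpG and treatment. Its 4 CpGs averaged 22.7% after saline and 39.4% after betamethasone (16.6 points, SD 3.17). Among the 10 leading gains the mean difference ran from 14.7 to 49.3 points, on 8 scaffolds, with 2 to 18 CpGs each.

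The largest loss at PND1 was on scaffold_0 at 62694867 to 62694884, where 3 CpGs averaged 54.5% after saline and 6.67% after betamethasone, a difference of -47.9 points (SD 6.97), at only 15 reads after betamethasone and 22 after saline. The 2 CpGs on scaffold_10 at 47593463 to 47593483 averaged 95.1% and 63.6% (-31.5 points, SD 17.8), and the one with at least 20 reads in both treatments differed by -18.9 points. On the same scaffold at 45822346 to 45822409, 4 CpGs with 51 to 60 reads averaged 32.1% after saline and 13.5% after betamethasone (-18.6 points, SD 0.70). Also on scaffold_10, at 32971346 to 32971389, 4 CpGs with 79 to 116 reads averaged 43.8% and 28.5% (-15.3 points, SD 2.52). A pair of CpGs on scaffold_184 at 173410 to 173433 averaged 98.9% after saline and 82.9% after betamethasone (-16.1 points, SD 4.13); with the other CpGs less than 10000 bp apart joined to it, the mean was -2.97 points. The 10 leading losses ran from -12.3 to -47.9 points on 7 scaffolds. In the authors' deposited table, 8 of the 10 gains and 8 of the 10 losses held at least 1 CpG with a first p-value under 0.05. The regions were picked for their size in the same reads, so these counts are no separate support. Over the listed CpGs, first p-values followed those of Fisher's exact test on the summed reads (Spearman's rho 0.836).

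**Figure D1:**
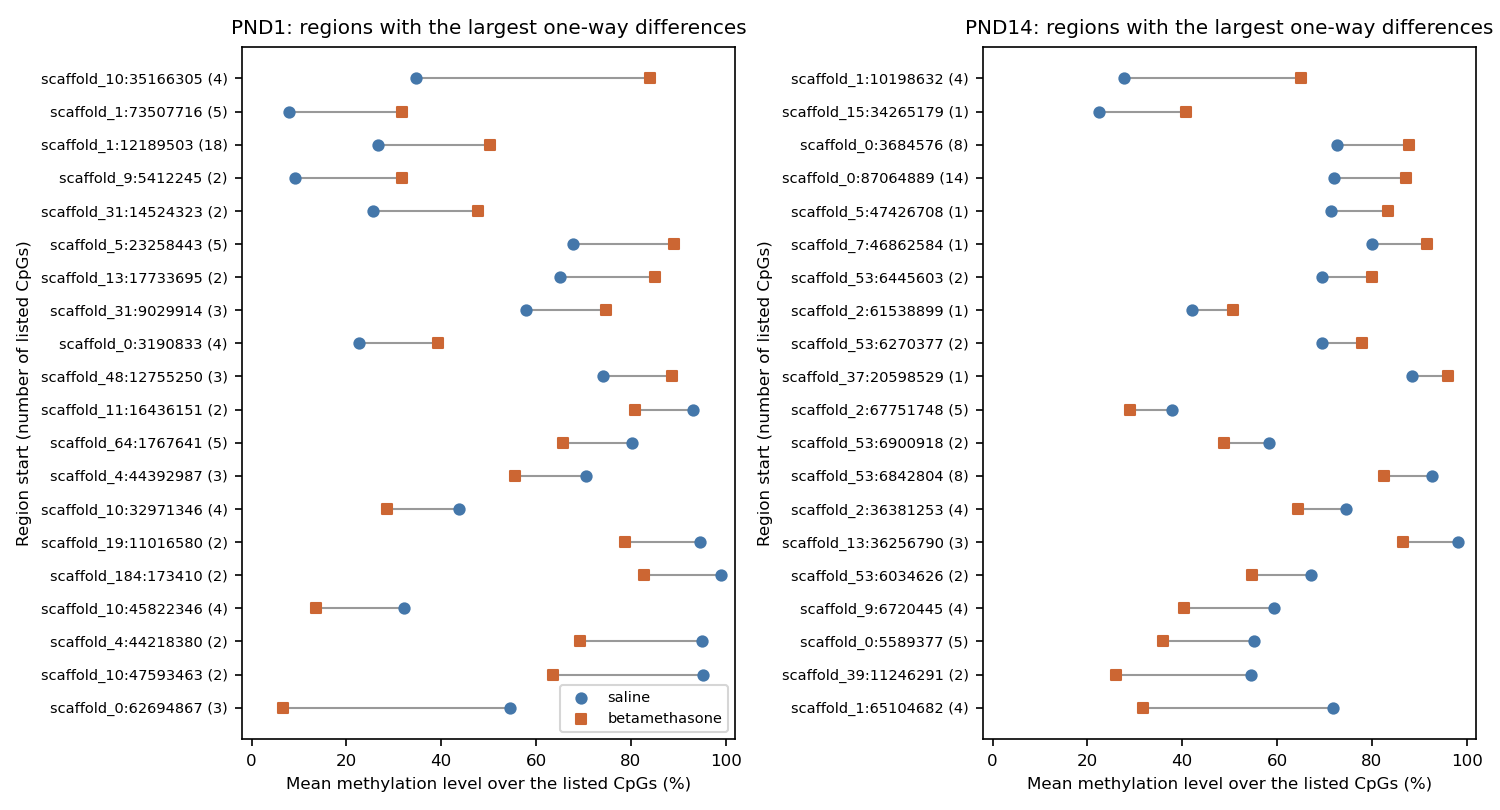
Each row is a region, named by scaffold and first position with its number of listed CpGs, and the horizontal axis is the mean methylation level in percent, with circles for saline and squares for betamethasone. PND1 is on the left and PND14 on the right, and the widest gaps are 49.3 points (scaffold_10 at 35166305) and -47.9 points (scaffold_0 at 62694867) at PND1 and -40.1 points (scaffold_1 at 65104682) at PND14.

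The PND1 table listed 4622 CpGs on 149 scaffolds, each with an FDR under 0.05 in the authors' deposited table. Of these, 2306 were more methylated and 2296 less methylated after betamethasone, and 20 were equal. Neighbouring CpGs less than 1000 bp apart were joined into 814 clusters, of which 407 of the 813 with a direction were higher (50.1%, exact 95% interval 46.6% to 53.6%; exact two-sided binomial p = 1). Most differences were small: the median size was 2.87 points, 632 CpGs differed by at least 10 points, and 158 by at least 20 points (93 higher, 65 lower). The median counting error of a difference was 4.26 points (SE from the summed reads alone). Mean methylation over the listed CpGs was 62.0% after betamethasone and 61.7% after saline, a difference of 0.28 points (95% bootstrap interval over clusters -0.08 to 0.67).

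Fisher's exact test on the summed reads, a two-sided test of the pooled libraries that leaves out variation between animals, singled out 7 CpGs at PND1 after Benjamini-Hochberg adjustment over the 4622. These CpGs had already been called from the same reads, so p-values adjusted over the list, at either age, rank its CpGs and can be too small as a test over all CpGs measured. The first pair lay on scaffold_67, at 7858871 (57.1% of 140 reads after saline, 88.7% of 106 after betamethasone, adjusted p = 0.000199) and at 7858889 (56.4% and 84.0%, adjusted Fisher's exact p = 0.00615). In the authors' deposited table this pair, unlike the other 5 CpGs, had first p-values over 0.05 (0.0906 and 0.0941). The second pair was on scaffold_0, at 81521679 (50.9% of 401 reads and 65.6% of 462, adjusted p = 0.0145) and 81521686 (52.6% and 66.0%, adjusted Fisher's exact p = 0.0466). On scaffold_117 at 3776067 the level was 15.2% of 46 reads after saline and 60.3% of 58 after betamethasone (adjusted Fisher's exact p = 0.00615). The CpG on scaffold_0 at 3190902, inside the deeply read gain described above, had 18.1% of 160 reads and 39.5% of 185 (adjusted Fisher's exact p = 0.0165). The only one lower after betamethasone was on scaffold_25 at 26209818, with 59.7% of 144 reads after saline and 36.0% of 178 after betamethasone (adjusted Fisher's exact p = 0.0230). Without adjustment 320 CpGs (6.92%) had a Fisher p under 0.05. In the authors' deposited table, 364 CpGs (7.88%, exact 95% interval 7.11% to 8.69%) had a first p-value under 0.05, and 0 after Benjamini-Hochberg adjustment of that p-value over the listed CpGs. On simulated reads at these coverages, drawn without variation between animals, the adjusted Fisher test found 0% of differences of 10 points, 33% of 20 points and 89% of 40 points. The differences were placed only at CpGs of intermediate level, so these shares do not cover CpGs near full or no methylation.

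At PND14 the region with most listed CpGs among the 10 leading gains was on scaffold_0 at 87064889 to 87065160. All 14 of its CpGs were higher after betamethasone, which the rule for picking regions requires. The region had means of 72.1% after saline and 87.2% after betamethasone (15.1 points, SD 10.02). It held both CpGs that passed the adjusted Fisher test at this age, at 87065049 (58.5% and 90.8% of 65 reads each, adjusted p = 0.0357) and 87065059 (56.1% of 66 reads and 90.8% of 65, adjusted p = 0.0164). On scaffold_0 at 3684576 to 3684678, 8 CpGs with 85 to 140 reads averaged 72.7% after saline and 87.9% after betamethasone (15.2 points, SD 3.11). The largest gain, on scaffold_1 at 10198632 to 10198664, rested on 18 and 20 reads: its 4 CpGs averaged 27.8% and 65.0% (37.2 points, SD 11.9). Only 5 of the 10 leading gains at PND14 had more than 1 CpG. The other 5 were single CpGs, among them scaffold_15 at 34265179 (22.4% and 40.8% of 49 reads each).

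The largest loss at PND14 was on scaffold_1 at 65104682 to 65104720, where 4 CpGs averaged 71.9% of 16 reads after saline and 31.8% of 11 after betamethasone (-40.1 points, SD 18.6). On scaffold_39 at 11246291 to 11246309, 2 CpGs averaged 54.5% and 25.9% (-28.6 points, SD 4.55). On scaffold_0 at 5589377 to 5589428, 5 CpGs averaged 55.2% and 36.0% (-19.2 points, SD 6.80), and on scaffold_9 at 6720445 to 6720693, 4 CpGs averaged 59.4% and 40.5% (-18.9 points, SD 7.77). The latter was -6.37 points when CpGs less than 10000 bp apart were joined. The leading loss with most CpGs, 8 on scaffold_53 at 6842804 to 6843448 in a dense block of calls, averaged 92.6% after saline and 82.5% after betamethasone (-10.04 points, SD 4.81). The mean difference was -0.32 points when CpGs less than 10000 bp apart were joined. In the authors' deposited table, 3 of the 10 leading gains and 3 of the 10 leading losses held a CpG with a first p-value under 0.05. As at PND1, these regions were picked for their size in the same reads.

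**Figure D2:**
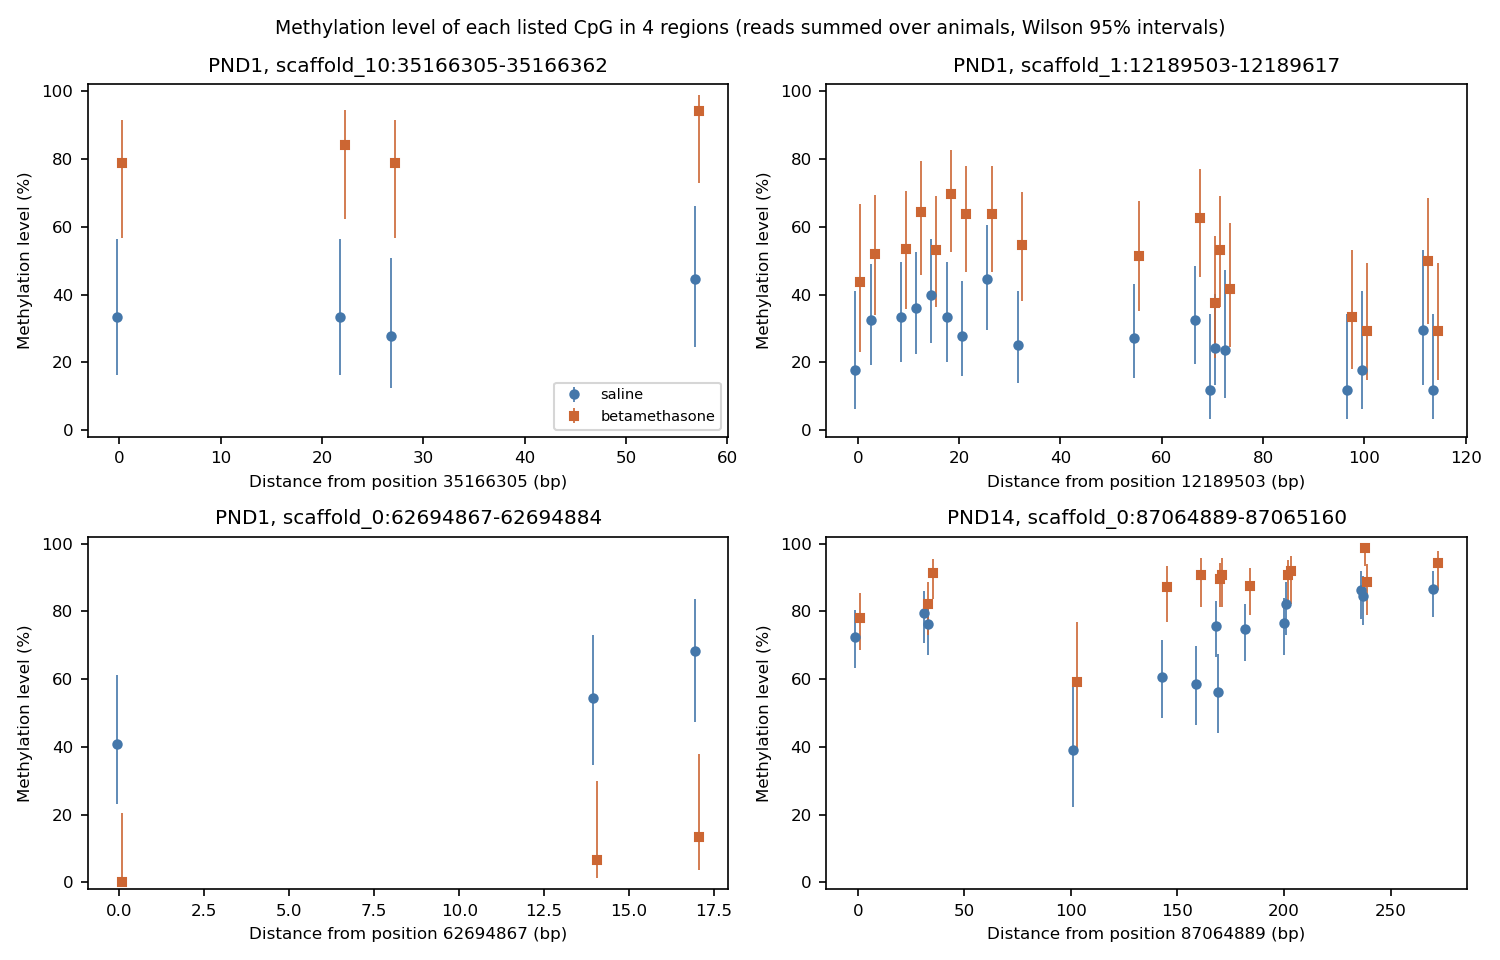
Each panel plots the methylation level in percent (vertical axis) of every listed CpG of a region against its distance in bp from the first one, with circles for saline, squares for betamethasone and bars for Wilson 95% intervals of the summed reads, which cover counting error only. In the region on scaffold_0 at 87064889 (PND14) the gap is widest at 87065059, with 56.1% and 90.8%, and all 18 CpGs on scaffold_1 at 12189503 (PND1) are higher after betamethasone. The rule that picked the regions took only those whose CpGs all moved the same way.

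The PND14 table listed 2005 CpGs on 75 scaffolds, 948 of them more and 1048 less methylated after betamethasone and 9 equal. They formed 277 clusters, of which 122 of the 275 with a direction were higher (44.4%, exact 95% interval 38.4% to 50.5%; exact two-sided binomial p = 0.0702). This share was lower than 50% in the exact binomial test with single CpGs as the unit (47.5%, p = 0.0267), with clusters less than 100 bp apart (45.2%, p = 0.0366) or 10000 bp apart (40.8%, p = 0.0207), and without the dense blocks (42.2%, p = 0.0439). It was not separated from 50% at an FDR under 0.01 (48.7%, exact binomial p = 0.811), at differences of at least 20 points (44.4%, p = 0.551) or on scaffolds with at least 10 listed CpGs (44.7%, p = 0.103). The test on single CpGs treats neighbours as independent, which they are not, so its p is too small. All of these tests count clusters or CpGs of the same animals and leave out variation between animals. The median difference was 3.49 points in size against a median counting error of 5.67 points, and 84 CpGs differed by at least 20 points (46 higher, 38 lower). Mean methylation was 59.7% after betamethasone and 59.98% after saline (-0.24 points, bootstrap interval -0.85 to 0.36). In the authors' deposited table, 115 CpGs (5.74%, exact 95% interval 4.76% to 6.84%) had a first p-value under 0.05, and 0 after Benjamini-Hochberg adjustment. That interval includes a share of 0.05, which evenly spread p-values would give if no CpG differed. The PND1 interval (7.11% to 8.69%) lay above it. Both intervals treat CpGs as independent, which they are not. The CpGs were also listed because they had been called, which can by itself change this share. The comparison with 0.05 therefore does not decide whether CpGs differed at either age. Fisher's exact test gave 94 CpGs (4.69%) without adjustment. In simulated reads at the PND14 coverages, the adjusted test found 1% of differences of 10 points, 14% of 20 points and 77.5% of 40 points, again placed only at CpGs of intermediate level.

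A few stretches of the genome held a large part of both tables. At PND1, scaffold_4 carried 291 listed CpGs between 43658097 and 43745840 and 1042 between 43966052 and 44592889, and scaffold_3 carried 113 between 19719421 and 19896779. Together these 3 blocks had 1446 CpGs, 31.3% of the table. At PND14, scaffold_53 carried 134 listed CpGs between 5918184 and 6526087 and 923 between 6676673 and 6977785, which is 52.7% of the table. Higher and lower CpGs lay side by side in the blocks: 708 and 731 at PND1, and 521 and 533 at PND14. The mean difference was -0.26 points in the PND1 blocks (bootstrap interval -0.73 to 0.20) and 0.08 points in the PND14 blocks (-0.66 to 0.86). Outside the blocks it was 0.53 points at PND1 (0.05 to 1.04), the only one of these 4 intervals that left out 0, and -0.60 points at PND14 (-1.53 to 0.36). These intervals leave out variation between animals. In the authors' deposited table, 78.5% of block CpGs at PND1 had an FDR under 5e-06, against 8.12% of the others, while a first p-value under 0.05 stood at 5.26% of block CpGs and 9.07% of the others. At PND14 the FDR was under 5e-06 at 34.6% of block CpGs and 5.91% of the others, but at only 8.21% in the block from 5918184. A first p-value under 0.05 stood there at 4.26% of all block CpGs and 7.38% of the others. At PND1 the CpGs under 5e-06 are the 1393 whose FDR was deposited as 0, while at PND14 only 15 CpGs have an FDR of 0. The cutoff therefore does not mean the same at both ages. The blocks were defined after the positions had been seen.

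**Figure D3:**
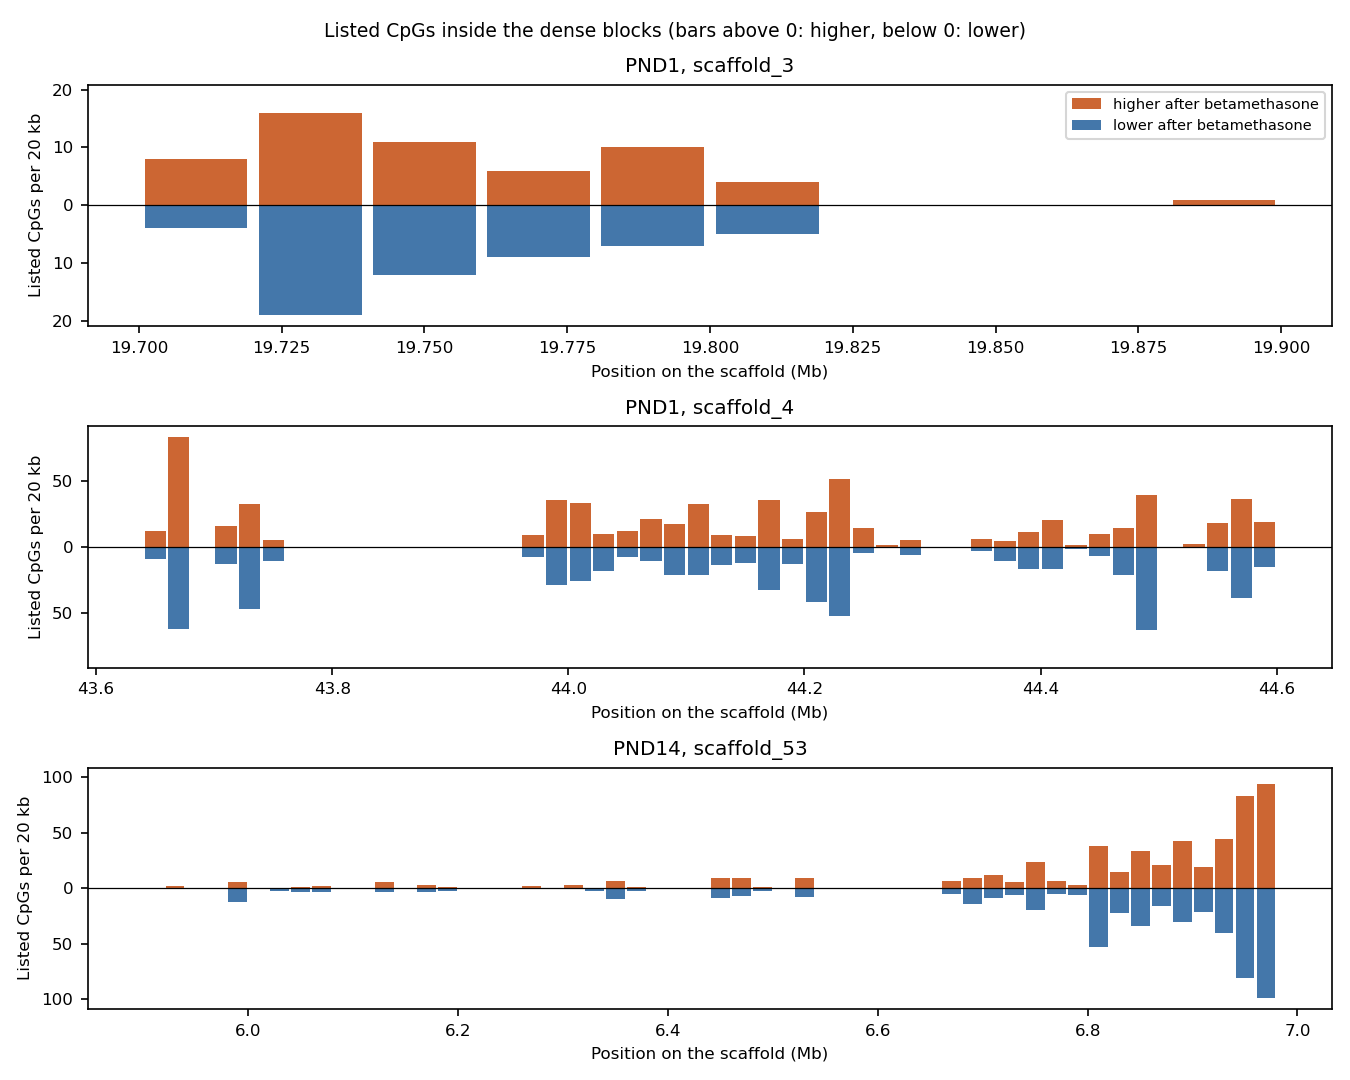
The horizontal axis is the position in Mb on scaffold_3 and scaffold_4 (PND1) and scaffold_53 (PND14), and bars give the listed CpGs per 20 kb, upward for those higher and downward for those lower after betamethasone. Bars of similar height stand on both sides of 0, as in the 20 kb of scaffold_53 from 6960000, with 94 higher and 99 lower.

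The 1298 listed CpGs of PND1 whose level, averaged over the treatments, lay between 20% and 80% had means of 58.4% after betamethasone and 57.2% after saline (1.28 points, bootstrap interval 0.23 to 2.43), but 205 of their 386 clusters were higher (53.1%, exact binomial p = 0.242). The 1052 CpGs below 20% had a mean difference of -0.10 points (-0.36 to 0.16) and the 2272 above 80% one of -0.12 points (-0.41 to 0.18). At PND14 the mean difference was -0.49 points (-2.09 to 1.02) in the 655 CpGs between 20% and 80%, -0.12 (-0.59 to 0.31) below and -0.13 (-0.62 to 0.40) above.

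Adjacent listed CpGs less than 1000 bp apart shared their direction in 54.6% of 3775 pairs at PND1, against 50.0% when directions were permuted over CpGs (two-sided permutation p = 1e-05, the smallest that 100000 permutations can give). At PND14 the share was 53.8% of 1717 pairs against 50.1% (permutation p = 0.00215). Inside the dense blocks of PND1 the share was 52.0% (permutation p = 0.156), and in those of PND14 53.2% (permutation p = 0.0454). Among the CpGs that differed by at least 20 points (158 at PND1 and 84 at PND14) it was 84.2% at PND1 and 76.9% at PND14. Adjacent CpGs of these small sets can share reads as well. The sharing was at short range, where a read can cover both CpGs: 56.4% of pairs 2 to 100 bp apart at PND1 and 55.8% at PND14, but 49.7% and 44.7% of pairs more than 100 and less than 1000 bp apart (permutation p = 0.886 and 0.126). Inside the dense blocks, pairs 2 to 100 bp apart shared their direction in 53.6% at PND1 (permutation p = 0.0307) and 55.1% at PND14 (permutation p = 0.00791). All CpGs of a cluster had the same direction in 149 of 668 clusters with at least 2 CpGs at PND1 (75 higher, 74 lower), where permuted directions gave a mean of 120 (permutation p = 0.00088). At PND14 it was 32 of 224 clusters (9 higher, 23 lower) against 31.1 (permutation p = 0.911), or 78 against 64.6 with clusters less than 100 bp apart (permutation p = 0.0372). These permutations treat CpGs as independent. CpGs on the same reads share counting error, so an excess over permuted directions does not by itself show a difference between the treatments. Positions 1 bp apart are taken as both strands of a CpG, which are read from different DNA strands. Their levels correlated across 654 pairs at PND1 (Pearson's r = 0.92 over CpGs, which are not independent replicates), while the correlation of their differences between treatments was r = 0.01, and 0.13 across 290 pairs at PND14. The strands differed in the same direction in 328 of 650 pairs (50.5%, exact 95% interval 46.5% to 54.4%) at PND1 and in 149 of 288 (51.7%, 45.8% to 57.6%) at PND14. Where at least 1 strand differed by at least 10 points, 62 of 116 pairs (53.4%, exact binomial p = 0.516) went the same way at PND1. At PND14 it was 49 of 85 such pairs (57.6%, exact binomial p = 0.193).

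No CpG was listed at both ages: 0 of the 4622 PND1 positions and the 2005 PND14 positions were shared, and 0 lay within 1 bp of each other. The tables had 58 of 166 scaffolds in common. Within 1000 bp of each other lay 19 CpGs of PND1 and 31 of PND14, in 2 places. On scaffold_42, 5 PND1 CpGs at 5825830 to 5825861 lay inside a PND14 cluster of 26 CpGs at 5825119 to 5826465. That place was nearly unmethylated, with 0.68% after betamethasone and 0.25% after saline at PND1, and 6.46% and 6.23% at PND14. On scaffold_67, 14 PND1 CpGs at 9123772 to 9123900 had a mean difference of -0.09 points (SD 7.75), and 5 PND14 CpGs at 9124061 to 9124086 one of -3.72 points (SD 3.88). None of the listed CpGs of either age lay in a dense block of the other. The share of clusters higher after betamethasone differed by -5.70 points between PND14 and PND1 (44.4% and 50.1%), a difference that Fisher's exact test did not separate from 0 (two-sided p = 0.109), though it did with clusters less than 10000 bp apart (-9.78 points, Fisher's exact p = 0.0286). The tables hold called CpGs and not the tested ones, so the number of shared positions that chance would give was not computed.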

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

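The direction of one-way clusters differed between the ages, in a test chosen after the result was seen. Of the clusters whose CpGs all moved the same way, 74 of 149 were lower after betamethasone at PND1 and 23 of 32 at PND14, such as scaffold_1 at 65104682 (-40.1 points) and scaffold_0 at 5589377 (-19.2 points). A two-sided Fisher's exact test of that difference gave p = 0.0308, or 0.0615 after Benjamini-Hochberg adjustment over the 2 main comparisons between the ages. That adjustment covers neither the alternatives below nor the choice of the test after its result was seen. The number of one-way clusters at PND14 did not stand above permuted directions (32 against 31.1, permutation p = 0.911), but it did with clusters less than 100 bp apart (78 against 64.6, permutation p = 0.0372). Over 5 alternatives (an FDR under 0.01, at least 20 reads, no dense blocks, clusters less than 100 or 10000 bp apart) the same Fisher's exact test gave p from 0.00569 to 0.19. The tests count clusters of the same animals and leave out variation between animals. The permutations also leave out that neighbouring CpGs can share reads. No explanation was tested.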

How the results depend on the processing

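The dense blocks, first p-value, Fisher and strand alternatives were chosen after seeing the data, as were clusters less than 10000 bp apart for the named regions. The count of called CpGs at PND1 (4622) was 2648 at an FDR under 0.01, 158 at a difference of at least 20 points, 364 with a first p-value under 0.05 and 7 by the adjusted Fisher test. At PND14 (2005) the count was 84 at 20 points, 948 without the dense blocks, 115 by the first p-value and 2 by Fisher. Each alternative tightens the call, replaces its test or leaves out CpGs by construction. The higher share at PND14 (44.4%, p = 0.0702) passed 0.05 in the exact binomial test without the blocks (42.2%, p = 0.0439), with single CpGs (47.5%, p = 0.0267), with clusters less than 100 bp apart (45.2%, p = 0.0366) and less than 10000 bp apart (40.8%, p = 0.0207). It was not past it at an FDR under 0.01 (48.7%, p = 0.811), at 20 points (44.4%, p = 0.551) or on scaffolds with at least 10 CpGs (44.7%, p = 0.103), all in the exact binomial test, and the single-CpG p ignores dependence of neighbours. Clusters less than 10000 bp apart also took the difference between the ages past it (-9.78 points, Fisher's exact p = 0.0286). The cause was not tested. The PND1 share stayed between 49.4% and 54.0% and never passed. PND1 CpGs near a PND14 CpG numbered 5 at up to 100 bp and 19 at up to 1000 bp. PND14 CpGs near a PND1 CpG numbered 2 and 31. The PND1 share crossed 50% with clusters less than 100 bp apart (49.4%) and at 20 points (49.5%). All 38 remaining values of main results, these included, kept their side of the threshold or lay within 1.5 times the count. Of the 40 named regions, 2 reversed with clusters less than 10000 bp apart: scaffold_53 at 6445603 (-1.04 points) and 6900918 (0.53 points), because other CpGs joined. Another 7 changed by more than their SD there, among them scaffold_4 at 44218380 (-0.45 points), scaffold_184 at 173410 (-2.97), scaffold_53 at 6842804 (-0.32) and scaffold_9 at 6720445 (-6.37), as did 6 regions at 20 points and 1 at 20 reads (scaffold_31 at 9029914, 1.18 points). Within their SD but over 1.5 times smaller at 20 reads were scaffold_10 at 47593463 (-18.9), scaffold_19 at 11016580 (-4.85) and scaffold_13 at 36256790 (-1.49). At least 20 reads left 29 regions with a value, without the largest gain and loss of either age, and an FDR under 0.01 left 19. Depth limits the test per CpG: at 20 points it found 33% of differences simulated at CpGs of intermediate level at PND1 and 14% at PND14.

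No paired analysis was possible because the tables give no value per animal; for the same reason no animal was left out and treatments were not reshuffled. Not run were the minimum of 5 reads, since every listed CpG has at least 10, and the alternatives that need a genome. Direction agreement has no value at shared CpGs or within 1 bp. Within 1000 bp only 2 places are left, both with mean differences of the same sign at the 2 ages. Each of these means was smaller in size than its SD over CpGs, so the signs carry little weight. Examples are 0.24 points (SD 4.40) on scaffold_42 at PND14 and -0.09 points (SD 7.75) on scaffold_67 at PND1.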

Other observations

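The coverage test of the dense blocks was chosen only after coverage had been seen, and the simulated differences of 1, 2 and 3 points after the strand result; the bounds of the other tests here were set before their results. The blocks on scaffold_3, scaffold_4 and scaffold_53 hold 31.3% of the PND1 and 52.7% of the PND14 table, with higher and lower CpGs in near-equal number. If the treatments differed at all these CpGs, both strands would tend to differ alike: in simulated reads, drawn as independent, differences of 1, 2, 3 and 5 points gave 54.4%, 60.7%, 67.6% and 79.5% of pairs in the same direction at PND1 and 53.3%, 59.5%, 66.2% and 76.8% at PND14. The strands went the same way in 48.6% of pairs in the PND1 blocks (exact 95% interval 41.9% to 55.4%). In the PND14 blocks it was 51.0% (42.8% to 59.1%). Both intervals lie below the bound of 60%, which, if reads are independent, argues against a true difference of about 3 points at all block CpGs. Fewer independent reads would bring the simulated shares nearer to 50%. The median observed size there (3.14 and 3.27 points) includes counting error. Outside the blocks the strands went the same way in 51.4% of pairs at PND1 (46.6% to 56.2%) and 52.6% at PND14 (43.8% to 61.2%). The blocks thus did not stand apart from the other listed CpGs in this test. Over all strand pairs, simulated differences of 1, 2 and 3 points gave 56.7%, 64.5% and 71.5% at PND1. At PND14 they gave 53.3%, 58.9% and 65.3%. The observed intervals over all pairs were 46.5% to 54.4% at PND1 and 45.8% to 57.6% at PND14. If reads are independent, this argues against a true difference of about 2 points at PND1 and 3 points at PND14 at all paired CpGs. Reads of collapsed repeat copies would raise coverage, but block CpGs had 0.945 times the median coverage of the others at PND1 (bootstrap interval 0.794 to 1.08) and 1.05 times at PND14 (0.890 to 1.30). In the blocks a difference of 1 point stays open, as do 2 points at PND14, where the simulated share lies just above the interval, and differences at a part of the block CpGs.

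Few listed CpGs had a first p-value under 0.05 (7.88% and 5.74%), although every one was called. A candidate explanation is that the second p-value and the FDR come from a CpG's neighbours and not from the CpG alone. Second p-values of adjacent listed CpGs less than 200 bp apart had a Spearman's rho of 0.960 at PND1 and 0.985 at PND14, while first p-values had 0.07 and 0.10. The PND1 second p-values are heavily tied, with 9 distinct values against 940 at PND14, so the PND14 rho carries more weight. These values are what the explanation needs, and a listed CpG may then differ little by itself; the authors' method is not given in the sources used here.

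No position was listed at both ages. One explanation is that common positions were taken out of clusters that both ages share, which would leave the CpGs of the ages interleaved. Inside the span of a cluster of the other age lay 5 PND1 CpGs, all on scaffold_42, and 0 PND14 CpGs, both under the bound of 20. This argues against such a removal from clusters otherwise shared. Removal of whole clusters, and a real difference between the ages, stay open and were not tested.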
